A study of Homo sapiens with 12 samples.

How the data were processed

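MicroRNA levels were measured with a NanoString assay, in which barcoded probes are counted without amplification, in total RNA of 2 human acute myeloid leukaemia cell lines. Each line carried either a lentiviral short hairpin RNA against MUC1 or a scrambled hairpin, per the labels' protocols, with 3 samples in each of 4 groups. The deposited values are probe counts for 798 human miRNA probes in 12 samples. They were read as counts from the values themselves, since all are whole numbers and their totals differ between samples. The counting software, any background correction and any scaling between lanes are not given in the sources used here. The smallest deposited count was 1, no value was 0, and 15 probes were at 1 in all 12 samples. Some probes moved between 1 and high values within a group, such as let-7a-5p at 1, 395 and 78 in silenced MOLM-14. Rounded values with background subtracted from some probes would look alike, so the deposited counts may not be raw for every probe. No control probes were used here, so the background of each probe is unknown.

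Samples were grouped by the line and hairpin in their titles and transduction labels. For the silenced MOLM-14 samples the source names conflict with these: they read MUC1, MUC2 and MUC3 for replicates 1, 2 and 3. The titles and transduction labels say MUC1 for all 3, and that grouping was used. Probes with at least 30 counts in at least 3 of the 12 samples were tested, which kept 67 of 798. Counts were scaled with TMM factors over these probes and fitted in 1 edgeR quasi-likelihood model of 4 group means (edgeR 4.0.16, R 4.3.3). It gave 5 comparisons: the hairpin effect in MOLM-14, in THP-1 and as the mean of the lines, the difference between the lines' effects, and the difference between the scrambled lines. Adjusted p-values follow Benjamini-Hochberg over the 67 probes with a threshold of 0.05, and errors of log2 fold changes are standard errors. Deposited counts, not scaled here, are given as mean ± SD. Of 27 miRNA lists, the 10 with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), also with an estimated correlation, and with fry. A total of 21 probes name more than 1 miRNA and are reported under their joint name.

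The groups, tests, lists, count filter, most alternatives and the rule for naming miRNAs were chosen before the data were examined. Named were the 10 largest rises and 10 largest falls past the threshold in each line and in the mean of the lines, the 5 largest each way in the other comparisons, members of the PD-L1, miR-200 and miR-34 lists, up to 4 members of every other list, and the 5 miRNAs of highest level in each line. The text gives the leading values of these and summarises the rest. Alternatives were DESeq2 1.42.0, limma on log2 counts with a pseudocount of 1 or 10, scaling by totals or by the geometric mean of the top 100 probes, subtraction of 10 counts, other filters, sample weights, a replicate block, fits of only the groups compared, and leaving out each replicate. Chosen after seeing the data were a scaling on 630 background probes (above 1 and under 30 counts in all samples), called background scaling, and the averaging of samples that agreed within sampling noise. Levels of the background probes are given as the mean ± SD of library means over all 630. That SD is not the spread of single background probes, which can lie anywhere above 1 and under 30 counts.

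Library totals ranged from 9002 to 20418 counts and library medians from 10 to 15.5 counts, and 654 probes stayed below 30 counts in every sample. Counting error alone is therefore large for most probes, and changes of weakly expressed miRNAs were not detectable at this depth. The fit was tested on simulated data with the 67 tested probes held fixed. In MOLM-14 it recovered 54.0% of simulated 2-fold and 98.3% of 4-fold changes with 4.09% false calls, and in THP-1 50.3%, 97.0% and 2.39%. These changes multiplied the whole count of a probe, background included, with rises and falls in equal number. A real change acts only on the part above background, so recovery of real changes is likely lower for probes near background. In a first version of this test the count filter was run again on each simulated table, and 37.0% of calls in MOLM-14 and 34.6% in THP-1 were false. The fixed probe set was adopted after that, so the lower false shares hold for a filter that does not depend on the simulated changes. The real filter was run on the same 12 samples as the tests, so the lower shares need not hold for the real calls. For example, miR-150-5p reached 30 counts only in the silenced MOLM-14 samples. When 25 of the 67 probes were lowered 4-fold in simulated silenced THP-1, TMM scaling gave a mean of 7.1 false rises and background scaling 0.4.

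No genome build is given in the sources used here, so no coordinates are printed. A table of RefSeq genes (GRCh38.p14) matched 41 of the 67 tested probes to a precursor gene through its synonyms.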

Results

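MUC1 is a transmembrane mucin studied as an oncoprotein in acute myeloid leukaemia, and the study asked how its silencing changes miRNAs, among them miRNAs that target the immune checkpoint ligand PD-L1. MOLM-14 and THP-1 are established human acute myeloid leukaemia lines of monocytic type. MUC1 mRNA and protein were not analysed here, so the silencing itself has no check in these values. Total counts were 13671 ± 3218 (SD, n = 3) in silenced MOLM-14, 14914 ± 2738 (n = 2) in scrambled MOLM-14, 11048 ± 1853 (n = 3) in silenced THP-1 and 18550 ± 1691 (n = 3) in scrambled THP-1. Scrambled MOLM-14 samples 2 and 3 did not differ significantly from sampling noise (chi-square over its degrees of freedom 1.08, p = 0.0521, over all probes and 1.23, p = 0.0951, over tested probes), while the other pairs of that group did. They were counted as 1 sample in means and SDs, although both ratios lie above 1 and separate samples are not excluded. The fits kept all 12 samples, and with that pair averaged 9 of the 11 MOLM-14 calls remained. The silenced THP-1 samples did not differ significantly over the tested probes either, with chi-square over its degrees of freedom at 0.944, 0.954 and 1.06. Over all probes samples 1 and 3 differed at the 0.05 level (1.09), while samples 1 and 2 (0.990) and samples 2 and 3 (1.03) did not. The 3 were kept apart, although the latter 2 ratios lie closer to 1 than that of the MOLM-14 pair counted as 1. Silenced MOLM-14 sample 2 stood apart from its group, with Pearson r of 0.654 with sample 1 and 0.697 with sample 3, against 0.961 between those. Over tested probes chi-square over its degrees of freedom was 19.2 and 15.9 for its pairs, against 2.84. The MOLM-14 fits included this sample. Nothing in the labels says that samples came from separate cultures, so p-values measure only the spread between these samples.

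**Figure D1:**
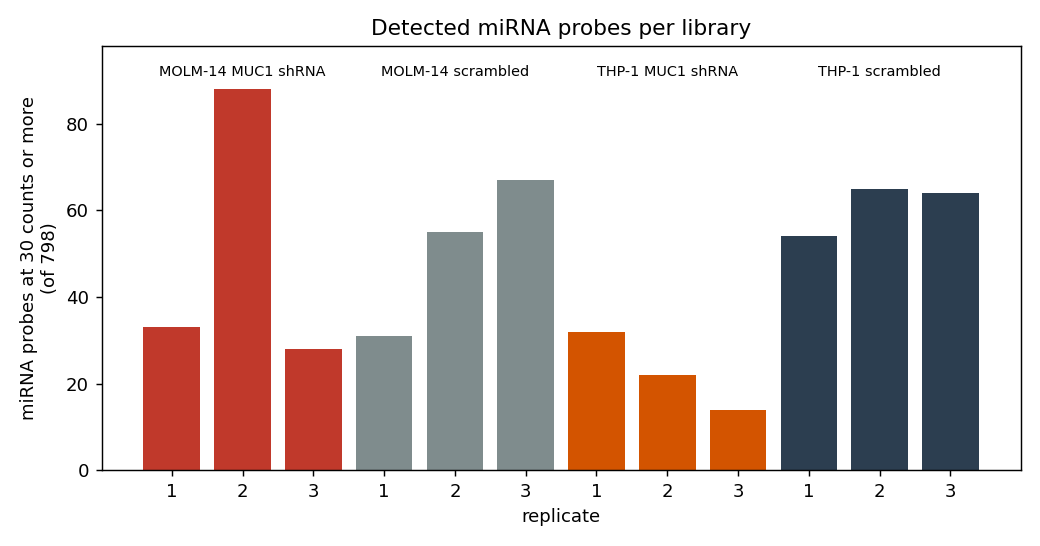
Number of miRNA probes, of 798, at 30 counts or more in each library, as bars by group and replicate. Silenced THP-1 libraries held 32, 22 and 14 such probes against 54, 65 and 64 in scrambled THP-1.

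The first comparison asked which miRNAs changed with MUC1 silencing in MOLM-14. miR-150-5p, which restrains the transcription factor MYB, rose from 13.0 ± 2.83 counts (SD, n = 2) to 76.0 ± 11.5 (n = 3), with a fitted log2 fold change of 2.74 ± 0.29. Its scrambled level was that of the 630 background probes (13.6 ± 1.34), so the size of this rise is uncertain and no fold is given. miR-4443 rose by 1.40 ± 0.28, and miR-181a-5p, a regulator of lymphoid development, by 0.80 ± 0.16, from 281.5 ± 91.2 to 435 ± 51.1 counts. let-7b-5p, of the let-7 family that represses RAS and HMGA2, fell by 0.81 ± 0.14 on the log2 scale, from 1203 ± 388 to 618 ± 170 counts. Log2 fold changes of other falls were -1.45 ± 0.25 for miR-93-5p, -1.34 ± 0.25 for let-7d-5p, -1.20 ± 0.21 for miR-15b-5p, -1.14 ± 0.27 for let-7i-5p and -1.08 ± 0.19 for miR-191-5p. Silenced counts were low for miR-93-5p (18 ± 5.57) and let-7i-5p (17.3 ± 8.02), with background probes at 12.1 ± 1.34, which makes the sizes of these 2 falls uncertain. In all 11 of 67 miRNAs passed, 4 higher and 7 lower (edgeR quasi-likelihood), and 22 had an unadjusted p under 0.05. miR-21-5p (0.64 ± 0.21) and let-7g-5p (-0.89 ± 0.29), each with an edgeR adjusted p of 0.0339, lost the call in 9 and 7 settings. Both lost it under background scaling, with DESeq2 and with only the groups compared, miR-21-5p also with total count and top 100 scaling, and let-7g-5p also with limma on log2 counts (pseudocount 1) and sample weights. They also lost it without some single libraries: both without silenced replicate 3 (0.47 and -0.90) and without scrambled replicate 2 (0.64 and -0.56), and miR-21-5p also without scrambled replicate 1 (0.57) or 3 (0.70). The number of calls was 21 without silenced replicate 1, and 15 and 10 without replicates 2 and 3, whose source names read MUC2 and MUC3 against MUC1 in their titles. miR-16-5p did not pass (2.65 ± 0.93, edgeR adjusted p = 0.0995), with 888 counts in silenced replicate 2 against a mean of 56 in the other 2, although it passed without silenced replicate 1 (3.13) or 3 (3.12).

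In THP-1 the same question gave larger falls. let-7b-5p fell 11.5-fold, from 3843 ± 884 to 197 ± 44.8 counts (SD, n = 3 each), a log2 fold change of -3.52 ± 0.16 (edgeR adjusted p = 1.84e-14), and -4.12 ± 0.27 under background scaling. miR-191-5p fell from 441 ± 66.3 to 25.7 ± 1.15 counts (-3.30 ± 0.22), and miR-15b-5p (-2.63 ± 0.23), let-7c-5p (-2.58 ± 0.24) and let-7d-5p (-2.40 ± 0.27) fell too. miR-223-3p, a marker of the myeloid lineage, fell (-1.63 ± 0.30), as did miR-23a-3p (-1.74 ± 0.25), miR-92a-3p of the miR-17-92 cluster (-1.55 ± 0.24) and miR-181a-5p (-1.23 ± 0.17). In silenced THP-1 library means of the background probes were at 12.5 ± 2.12 counts, with single background probes at up to just under 30. There these 7 were at 17.7 ± 1.53 (miR-15b-5p), 15.3 ± 3.06 (let-7c-5p), 13.7 ± 1.15 (let-7d-5p), 9 ± 1.73 (miR-223-3p), 13.3 ± 1.53 (miR-23a-3p), 18.7 ± 4.04 (miR-92a-3p) and 19.7 ± 2.52 (miR-181a-5p). The sizes of these falls are therefore uncertain, as counts near background do not show how much miRNA was left. The size for miR-191-5p is uncertain too, as its silenced counts lay under 30, within the range allowed for background probes. let-7a-5p was at the floor of 1 in all 3 silenced samples against 471, 913 and 434 counts, so no fold is given. miR-196a-5p, encoded in the HOX clusters, rose from 14 ± 7 counts, the level of background probes in scrambled THP-1 (14.1 ± 0.77), to 91 ± 13.5 (fitted value 3.47 ± 0.28), so no fold is given, and miR-1180-3p rose from 32.7 ± 3.51 to 68.7 ± 10.4 counts (1.83 ± 0.21).

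In THP-1 27 of 67 miRNAs passed, 11 higher and 16 lower (edgeR quasi-likelihood, 34 at an unadjusted p under 0.05). Background scaling moved the median log2 fold change from -0.03 to -0.61 and gave 33 calls, 2 higher and 31 lower, so the share of higher calls went from 40.7% to 6.06%. The 2 that stayed higher were miR-196a-5p (2.87 ± 0.33) and miR-1180-3p (1.24 ± 0.22). The other 9 had nearly equal deposited counts in both groups, such as 48.3 ± 17.2 and 44.7 ± 5.13 for miR-598-3p, and lost the call. Without silenced replicate 2, miR-922 (0.62), miR-192-5p (0.57), miR-1183 (0.52), miR-598-3p (0.51), miR-6721-5p (0.51) and miR-1299 (0.47) lost it too, as miR-2682-5p (0.69), miR-1299 (0.71) and miR-149-5p (0.63) did without silenced replicate 3. miR-149-5p lost it without silenced replicate 1 as well (0.63). Averaging the silenced samples into 1 left 15 calls, 2 higher and 13 lower, in a fit that assumes that this lone sample varies like the other groups. miR-155-5p (-0.75 ± 0.22) lost the call without scrambled replicate 1 (-0.33) or 2 (-0.47), and miR-25-3p (-0.60 ± 0.24) lost it in 9 settings, among them without any 1 of 5 of the 6 libraries, with DESeq2 and with top 100 and total count scaling. Under background scaling both passed with larger falls (-1.33 ± 0.24 and -1.18 ± 0.24, edgeR adjusted p = 0.000141 and 0.000451).

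**Figure D2:**
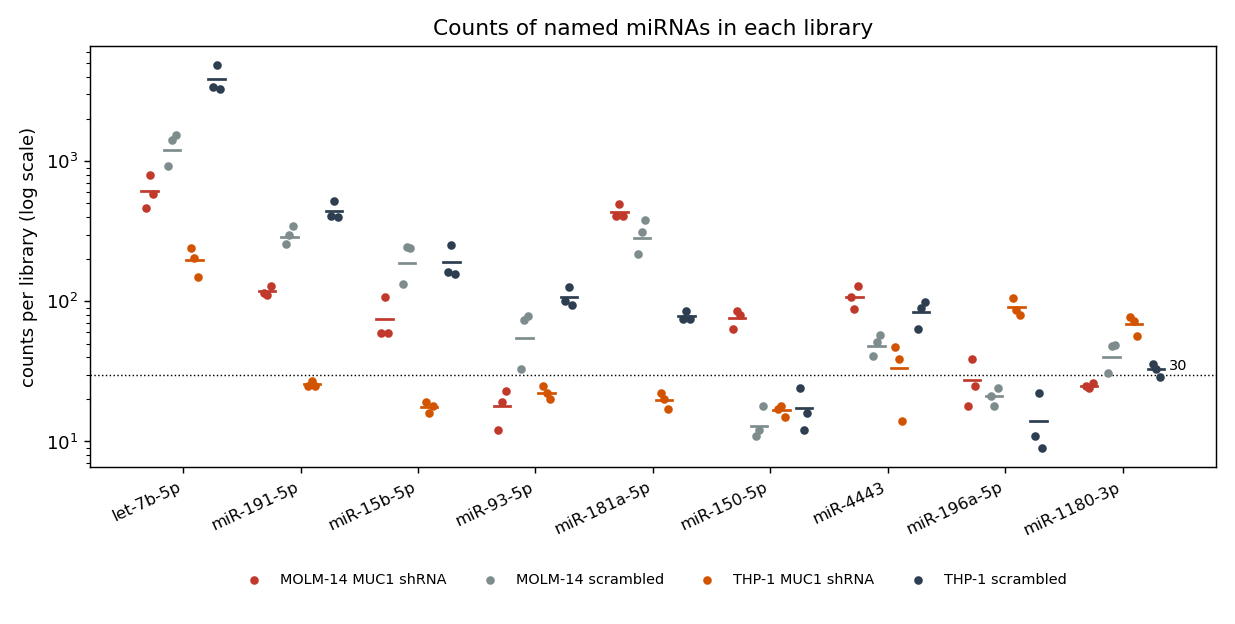
Counts of 9 named miRNAs in each library on a log scale, with points for replicates, short lines for group means and a dotted line at 30 counts. let-7b-5p lay at 150 to 239 counts in silenced THP-1 and at 3259 to 4860 in scrambled THP-1.

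let-7 was the only list to pass camera, at its preset correlation, in each line. In MOLM-14 4 of its 6 tested members fell and 2 did not pass, let-7a-5p (158 ± 209 against 414 ± 263 counts) and let-7c-5p (-0.14 ± 0.21), with a camera adjusted p of 0.00410 and adjusted p = 0.373 with an estimated correlation. In THP-1 all 6 fell (camera adjusted p = 0.000215, adjusted p = 0.373 with an estimated correlation), and in the mean of the lines all 6 fell (1.34e-05, adjusted p = 0.189 with an estimated correlation). Adjusted over the list alone, the counts were again 4, 6 and 6. The list of MYC-repressed miRNAs passed in THP-1 (camera adjusted p = 0.0311, adjusted p = 0.423 with an estimated correlation), and the 5 of its 8 tested members that fell were all let-7 members. let-7 members have near-identical sequences and the sharing of signal between probes is not settled by these values, so single members are uncertain. Silenced THP-1 libraries held 14 to 32 probes at 30 counts or more against 54 to 65 in scrambled THP-1, and under background scaling 31 of the 33 THP-1 calls were lower, so the let-7 fall there went with a fall of most called miRNAs. All 6 kept their direction under background scaling in each line.

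Other lists did not pass camera in any of the 3 comparisons. By fry, 3 lists passed in MOLM-14: let-7 (lower, adjusted p = 0.00651), miR-17-92 (lower, adjusted p = 0.00490) and lymphoid (higher, adjusted p = 0.000824). In THP-1 8 passed by fry, all lower, with let-7 and miR-17-92 each at an adjusted p of 6.42e-05. Of the miR-17-92 list and its paralogs, 1 of 5 tested members fell in MOLM-14 (miR-93-5p) and 3 of 5 in THP-1 (miR-25-3p, miR-92a-3p and miR-93-5p), the same counts as adjusted over the list alone. Of the myeloid differentiation list, 1 of 4 rose in MOLM-14 (miR-21-5p) and 3 of 4 fell in THP-1 (miR-155-5p, miR-223-3p and miR-23a-3p). Of the lymphoid list, 2 of 4 rose in MOLM-14 (miR-150-5p and miR-181a-5p) and 1 of 4 fell in THP-1 (miR-181a-5p). Adjusted over the list alone, the counts of these lists did not differ. A total of 13 lists, among them epithelial, erythroid, muscle, neural and liver markers, had no tested member.

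The miRNAs that target PD-L1 were the study's named interest. Of 31 measured members of the PD-L1, miR-200 and miR-34 lists, 22 stayed below 30 counts in every library, with a highest count of 28. miR-34a-5p had 14.7 ± 4.04 counts (SD, n = 3) in silenced and 22.3 ± 1.77 (n = 2) in scrambled MOLM-14, and 17.3 ± 9.02 and 24 ± 3.46 (n = 3 each) in THP-1. In a fit without the count filter its log2 fold change was -0.45 in MOLM-14 (95% interval -1.06 to 0.16) and -0.27 in THP-1 (-0.86 to 0.32). miR-200c-3p gave -0.02 (-0.66 to 0.62) and -0.01 (-0.65 to 0.63). Neither change was detectable at this depth. Of the 5 tested members of the PD-L1 list, miR-93-5p fell in MOLM-14, and miR-93-5p and miR-155-5p fell in THP-1, with the same counts adjusted over the list alone. The PD-L1 list did not pass camera in MOLM-14, THP-1 or the mean of the lines (adjusted p = 0.701, 0.417 and 0.366). By fry it passed as lower in THP-1 (adjusted p = 0.00799) and in the mean (adjusted p = 0.00696), but not in MOLM-14 (adjusted p = 0.317). miR-20a-5p/miR-20b-5p did not pass in THP-1 (-0.57, edgeR quasi-likelihood adjusted p = 0.0873), but passed under background scaling (-1.15, adjusted p = 0.0037), with sample weights (-0.55, adjusted p = 0.0338) and without the count filter (-1.11, adjusted p = 0.0122).

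The effects of the lines were then set side by side. Of 8 miRNAs past the threshold in both lines, 7 fell in both (let-7b-5p, let-7d-5p, let-7g-5p, let-7i-5p, miR-15b-5p, miR-191-5p and miR-93-5p) against 1.67 expected from independent lists (Fisher's exact test, one-sided p = 1.32e-05, across miRNAs, which are not independent). That expectation treats all 67 miRNAs as equally able to fall, which those near background were not. The overlap therefore does not separate a shared effect from a loss of signal in both lines. miR-181a-5p rose in MOLM-14 and fell in THP-1. Across the 67 miRNAs the log2 fold changes had Pearson r = 0.414 and Spearman rho = 0.280. Without let-7a-5p r was 0.356, and over all 798 probes, without the count filter, it was 0.106. In the mean of the lines 20 miRNAs passed, 6 higher and 14 lower (edgeR quasi-likelihood). Besides let-7a-5p, at the floor in silenced THP-1, the largest falls were miR-191-5p (-2.19 ± 0.14) and let-7b-5p (-2.16 ± 0.10). The size for miR-191-5p is uncertain, as its counts in silenced THP-1 lay under 30. The largest rises were miR-196a-5p (2.03 ± 0.20) and miR-150-5p (1.71 ± 0.22). Their sizes are uncertain, as each lay near background in 1 scrambled line or more. Each of these rises passed in 1 line only. miR-150-5p was at 16.7 ± 1.53 counts in silenced and 17.3 ± 6.11 in scrambled THP-1. miR-196a-5p did not pass in MOLM-14 (0.59 ± 0.28, edgeR adjusted p = 0.132). With background scaling 22 miRNAs passed in the mean of the lines, 2 higher and 20 lower, so the higher share went from 30% to 9.09%.

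The difference between the lines' effects passed for 18 miRNAs, 4 higher and 14 lower in THP-1 relative to MOLM-14 (edgeR quasi-likelihood). let-7b-5p differed by -2.71 ± 0.20 (-3.27 ± 0.35 under background scaling), let-7c-5p by -2.44 ± 0.32, miR-191-5p by -2.23 ± 0.28, miR-150-5p by -2.04 ± 0.43 and miR-181a-5p by -2.03 ± 0.23. miR-196a-5p differed by 2.88 ± 0.39 and miR-1180-3p by 2.31 ± 0.30. The sizes are uncertain for let-7c-5p, miR-150-5p, miR-181a-5p and miR-196a-5p, which lay near background in at least 1 group. The same holds for miR-191-5p, at 25.7 ± 1.15 counts in silenced THP-1, and miR-1180-3p, at 25 ± 1 in silenced MOLM-14. Background scaling gave 25 calls, 2 higher and 23 lower, a higher share of 8% against 22.2%, and averaging the silenced THP-1 samples into 1, with the spread taken from the other groups, left 11.

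**Figure D3:**
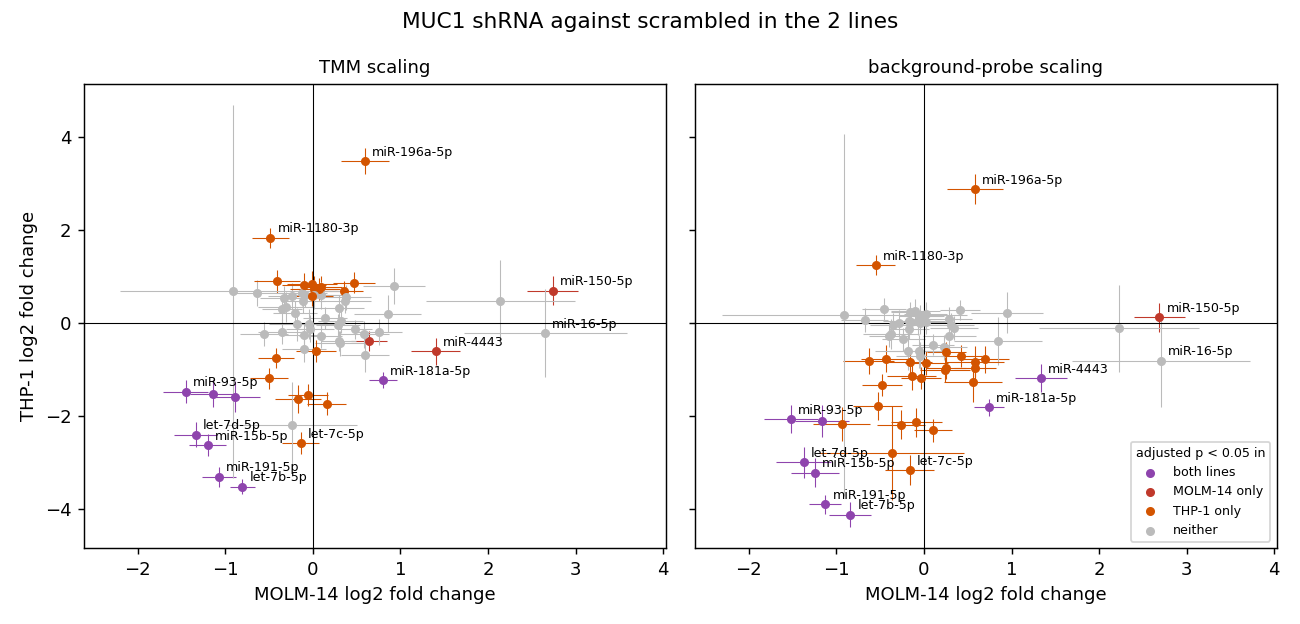
Log2 fold changes of MUC1 shRNA against scrambled in MOLM-14 (horizontal) and THP-1 (vertical) for the tested miRNAs other than let-7a-5p, with bars of 1 SE, under TMM scaling and under background scaling. let-7b-5p, miR-191-5p and miR-15b-5p lie below 0 on both axes in both panels, and miR-181a-5p lies above 0 in MOLM-14 and below 0 in THP-1.

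Scrambled THP-1 was compared with scrambled MOLM-14 as the starting level of each line. miR-181a-5p was lower in THP-1 by -2.07 ± 0.16 in log2 fold change (78.7 ± 6.35 against 281.5 ± 91.2 counts), and let-7b-5p was higher by 1.42 ± 0.14 (3843 ± 884 against 1203 ± 388). These were the 2 of 67 miRNAs that passed (edgeR quasi-likelihood, 17 at an unadjusted p under 0.05). Background scaling gave 5 calls, 4 higher and 1 lower (80% higher against 50%), a fit of only these groups gave 16, and the count was 5 without THP-1 scrambled replicate 2.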

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

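All tests of technical explanations in this part were chosen after the results were seen, and only the counts over other splits of the samples were planned.

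The effect of MUC1 shRNA differed between the lines, by the test of the difference itself (log2 fold change in THP-1 minus MOLM-14), for 18 miRNAs. It was lower in THP-1 for let-7b-5p (-2.71), let-7c-5p (-2.44), miR-191-5p (-2.23), miR-150-5p (-2.04), miR-181a-5p (-2.03), miR-4443 (-2.02), miR-23a-3p (-1.89), miR-92a-3p (-1.49), miR-223-3p (-1.46), miR-15b-5p (-1.42), miR-4454/miR-7975 (-1.29), let-7d-5p (-1.06) and miR-21-5p (-1.03). It was higher in THP-1 for miR-196a-5p (2.88), miR-1180-3p (2.31), miR-922 (1.30) and miR-629-5p (1.27), of which miR-629-5p lost the call in 6 settings and miR-922 in 2, background scaling among both. Sizes are uncertain where a group lay near background, as silenced THP-1 did for let-7c-5p, miR-23a-3p and miR-191-5p. let-7a-5p passed too (edgeR quasi-likelihood adjusted p = 0.0375), with silenced THP-1 at the floor of 1, and lost the call in 14 settings.

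Counts of calls were set against other splits of the same samples. For the difference between the lines, 8 of 100 splits gave at least the real 18 calls, with 25 as the highest other, so this count alone does not exclude chance. All 7 other splits as large kept the real THP-1 grouping, which leaves the THP-1 effect in the difference, so they do not measure chance alone. Drawn splits that kept neither line's grouping called 0. For the mean of the lines, 4 of 100 splits gave at least the real 20 calls, with 24 as the highest other, and all 3 others kept the real THP-1 grouping. The 10 splits of each 6 samples are too few for a share under 0.05: 1 of 10 splits reached the real 11 calls in MOLM-14 (highest other 1), 1 of 10 the real 27 in THP-1 (highest other 0) and 1 of 10 the real 2 between scrambled lines (highest other 0).

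Silenced THP-1 libraries held little miRNA signal: let-7b-5p took 1.67% to 1.89% of their counts against 18.0% to 23.8% in scrambled THP-1. Less miRNA signal of every kind could account for falls but would not raise a miRNA. Under background scaling the smaller of the miR-196a-5p and miR-1180-3p rises was still 1.24 ± 0.22. These were the 2 of 11 called rises that stayed called under that scaling, so this test could hardly fail, and the other rises lost the call. Before any scaling, counts of miR-1180-3p rose from 32.7 ± 3.51 to 68.7 ± 10.4, which less signal alone would not give. For the falls, equal loss predicts that every miRNA kept the same share of its background-free counts, and 2 versions of this test were run. The first covered 16 miRNAs besides let-7b-5p at 60 counts or more in scrambled THP-1, and left out let-7a-5p, which was above that level too. It argued against equal loss through miR-873-3p alone, which kept at least 77.9 ± 34.7% where let-7b-5p kept at most 5.76%. That margin of 2.08 SE was the largest of 14 and not corrected for their number (miR-612 kept 102 ± 11.3% at a background of 0 and 145 ± 391% at the highest). The second, restricted after a first result through such flat probes to 11 miRNAs called lower, gave 4.52% for miR-93-5p. It decides nothing, because the restriction removes the probes that equal loss forbids. As the first version rests on miR-873-3p alone, equal loss, unequal loss of signal and a MUC1 effect all stay open.

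The let-7 fall in MOLM-14 was weighed against the same loss of signal and against shared probe signal. Under background scaling, the median log2 fold change of 13 other miRNAs at 60 counts or more lay 0.68 above the let-7 median, more than the summed errors of 0.45, although 10 of the 13 were also lower. Between scrambled lines let-7b-5p was higher in THP-1 by 1.57 ± 0.24 with background subtracted, and the other 4 let-7 probes differed from it by a median of -1.43 ± 0.66. let-7c-5p went the same way (0.80 ± 0.21), while let-7d-5p (0.38 ± 0.39), let-7g-5p (-0.38 ± 0.61) and let-7i-5p (-0.12 ± 0.39) did not clearly follow. The lines may differ in their own let-7 levels, so this does not decide whether let-7b-5p signal on other probes caused their fall within MOLM-14. An effect of MUC1 silencing on let-7 in MOLM-14 may remain, as a hypothesis found and tested on the same data, and RNA input per library stays open.

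Silenced MOLM-14 replicate 2 held 41 probes at 30 counts or more that the tests did not use, among them miR-877-5p (350 counts), miR-548n (190), miR-219a-2-3p (147), miR-483-3p (104) and miR-548aa/miR-548t-3p (99). More RNA input is not a likely cause, since miRNAs at 60 counts or more in the other 2 libraries had a median ratio of 0.914 in replicate 2. RNA of erythroid cells is not either, since the highest listed erythroid probe had 18 counts there. Its source name reads MUC2 where its title reads MUC1, no other target was tested, and no biological explanation was tested. In silenced MOLM-14 replicate 3, miR-122-5p, a liver marker outside the tested probes, had 52 counts.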

How the results depend on the processing

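Background scaling and the averaging of alike samples were chosen after seeing the data. Of 65 named calls, 974 of 1050 values under the alternatives kept direction and call, 76 lost the call in the same direction, and 0 reversed. Of 343 values of the 22 named results that did not pass, 14 passed. Depth limits the rest: 654 of 798 probes stayed below 30 counts. The causes below were not tested, except that stricter filters test fewer probes (10 at 100 counts in 3 samples, 42 at 30 counts in 6) and averaging leaves fewer samples.

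With at least 100 counts in 3 samples, calls were 4 in MOLM-14, 5 in THP-1, 8 in the mean of the lines, 6 for the difference and 5 between scrambled lines, with 0 lists in each of the 3 silencing comparisons. With at least 30 counts in 6 samples the mean of the lines had 31 calls, 18 higher and 13 lower. Silenced THP-1 as 1 sample, assumed to vary like the other groups, gave 15 calls in THP-1 and 11 for the difference. Between scrambled lines there were 5 calls with total count scaling, 5 with background scaling, 14 with sample weights and 16 with only the groups compared, and the cause was not tested. List counts were 0 in each comparison with an estimated correlation, and 3, 8 and 9 with fry (MOLM-14, THP-1, mean). Without a filter they were 6 in THP-1 and 4 in the mean, and in THP-1 1 with camera on limma values and 1 with background scaling. The correlation of the lines' effects was 0.106 without a filter.

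Repeat numbers did not pair the samples: deviations of same-numbered samples correlated at 0.36, 0.41 and -0.22 in MOLM-14, 0.14, -0.42 and -0.24 in THP-1 and 0.087, 0.21 and -0.15 between the scrambled lines, and not every sample correlated best with its own number. With a replicate block, calls were 11 in MOLM-14, 26 in THP-1, 20 in the mean, 16 for the difference and 16 between scrambled lines (fitted on those 6 samples, where the fit without a block gave 16 as well), and list counts were 1, 2 and 1. With the block miR-25-3p in THP-1 (adjusted p = 0.0640) and miR-629-5p in the difference (adjusted p = 0.0700) lost the call.

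Leaving out each replicate gave 9 to 21 calls in MOLM-14 (21 without silenced replicate 1), 20 to 39 in THP-1, 19 to 29 in the mean, 14 to 27 for the difference and 2 to 5 between scrambled lines. List counts were 1 to 1 in MOLM-14, 2 to 2 in THP-1 and 1 to 2 in the mean, with 2 without silenced MOLM-14 replicate 2 or scrambled THP-1 replicate 3, and r was 0.313 to 0.467.

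All 31 reversals were among named miRNAs that did not pass, and the cause was not tested. Leaving out each replicate, log2 fold changes in MOLM-14 ran from -0.36 to 0.12 for miR-15a-5p, -0.34 to 0.15 for miR-20a-5p/miR-20b-5p, -0.43 to 0.10 for miR-192-5p and -0.037 to 0.35 for miR-23a-3p. In THP-1 they ran from -0.38 to 0.37 for miR-15a-5p, -0.39 to 0.17 for miR-16-5p and -0.30 to 0.14 for miR-125a-5p. In the mean they ran from -0.21 to 0.17 for miR-15a-5p and -0.11 to 0.20 for miR-125b-5p. In THP-1 miR-15a-5p was at 0.069 with top 100 scaling and miR-125b-5p at -0.28 with background scaling. In the mean miR-107 was at -0.18 with background scaling, and miR-125b-5p at 0.016 with DESeq2 and 0.011 with sample weights.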

Other observations

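In silenced MOLM-14 replicate 2, 17 probes had at least 60 counts and at least 5 times the mean of the other 2 silenced libraries, and together they took 19.1% of its counts. They included miR-16-5p (888 counts), let-7a-5p (395), miR-1290 (303) and miR-1246 (188), and 14 of the 17 stayed under 60 counts in all other 11 libraries. miR-1246 had 1 count on average in the other 2 silenced MOLM-14 libraries and 1 in every THP-1 library, but 14, 172 and 224 in scrambled MOLM-14, so its 188 counts were not unique to replicate 2.

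The correlation of the lines' log2 fold changes (r = 0.414) was reached by 1 of 100 splits of the samples within lines, the real one, with 0.409 as the highest other. Without let-7a-5p it was 0.356 and was reached by 3 of 100, with 0.375 as the highest other.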
